A study of Mesocricetus auratus with 64 samples.

How the data were processed

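The series holds 64 samples of golden hamster, 32 of long RNA and 32 of small RNA. All 32 long RNA libraries and the 2 small RNA libraries with tables of reads (WT-GV and WT-54PEA) were used, and the other small RNA samples were not analysed here. Per the labels' protocols, oocyte and embryo libraries were made by a Smart-seq2-like method from single oocytes or embryos, with 0.125 µL of a 1 in 100000 dilution of ERCC spike-in RNA added to each, and testis libraries from total RNA depleted of ribosomal RNA. The long RNA values are read counts per gene, made by the authors before they were deposited. Per the submitters' processing notes, STAR 2.7.1a, TopHat, Trim Galore and featureCounts were used upstream; the notes do not give the role of each for each library type. The small RNA files give the count of reads of each distinct sequence, as deposited by the authors. No file was mapped or counted again here.

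Each long RNA file had 32303 gene rows and 92 ERCC rows, and 31882 gene names matched a RefSeq symbol. Another 8 lines of 1 file that name no gene were dropped. No mitochondrial gene was among them. Gene counts of replicates 1 and 2 were 9792193 and 9094764 in WT-GV, 6481558 and 9017488 in KO-GV, 8928993 and 11031837 in WT-MII, 10322124 and 9382110 in KO-MII, 9218151 and 8826096 in WT-10PEA, 9282215 and 8360306 in KO-10PEA and 8518775 and 9000174 in KO-MII-D321. They were 8435278 and 7839878 in WT-1C-20PEA, 9104151 and 8184314 in KO-1C-20PEA, 5812078 and 4235441 in WT-33PEA, 6691910 and 5737284 in KO-33PEA, 6078063 and 7482076 in WT-54PEA and 2755240 and 1544198 in KO-54PEA. Testis replicates 1 to 3 had 34093389, 34147366 and 34257661 in WT-testis, and 31839549, 32892040 and 31572737 in KO-testis. ERCC counts stayed out of library sizes except where scaling used them, and made up 0.361% to 77.8% of the counts in oocytes and embryos. The Spearman correlation of the libraries of a group was 0.954 to 0.990 in testis, 0.962 in WT-GV, 0.943 in KO-GV, 0.914 in WT-MII, 0.734 in KO-MII, 0.701 in WT-33PEA, 0.532 in KO-33PEA, 0.822 in WT-54PEA and −0.143 in KO-54PEA.

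Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with TMM scaling, after filterByExpr, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. A gene that passed is called changed. The 26 oocyte and embryo libraries were fitted together as 13 group means, since 2 libraries per group give little information on their own, and the 6 testis libraries apart, since another kit was used. The fits tested 17294 and 18024 genes, with a common dispersion of 1.07 and 0.0806. Comparisons were KO against WT in testis and at each of 6 stages, the average of the 6 stage differences, an F test of the 5 differences between stages, the D321 set against WT MII and KO MII, and each step of the WT time course. The pooled fit takes 1 spread per gene for all stages, and a lone library left in a group is assumed to vary like the others. Where the libraries of late stages spread more than those of early ones, this can make p-values too small late and too large early. The replicates are libraries, and no animal is named for any of them.

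Standard errors are the log2 change over the root of the F statistic. For a gene without a count in a group, the text gives the fold against a floor of 3 counts over that group in place of the fitted change. No fold is given where a group had 1 to 3 counts. List medians are also given with absent genes at that bound where it differs.

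Gene lists were drawn up before the data were examined: piRNA pathway; small RNA machinery; DNA methylation and repeat silencing; spermatogonia, early meiosis, pachytene and later spermatocytes, spermatids; Sertoli, Leydig, peritubular and vascular cells, macrophages and leukocytes, blood, granulosa and cumulus cells; interferon response, p53 and apoptosis, stress response; maternal oocyte genes, maternal mRNA storage and decay, embryonic factors; ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrial dynamics, meiotic and mitotic spindle, and mitochondrial transcripts. These 25 lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with the correlation estimated, and with fry. Adjustment covered the 23 lists with 3 or more measured genes in testis and 322 tests in oocytes and embryos. Members that passed were counted with p adjusted over all genes tested and adjusted over the list alone. In oocytes and embryos camera passed in 34 tests, 3 with an estimated correlation, and fry in 54.

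Named genes follow a rule also set before the data were examined: Pld6, then Piwil1, Piwil2, Piwil3 and Ddx4. For each comparison it adds genes that passed, with a gene symbol, a mean of at least 5 CPM in the higher group and all libraries of a group above all of the other. The largest rises and falls among these were taken (10 each way in testis, 8 in the average, 5 per stage and 4 per WT step), and up to 3 members per list with the smallest adjusted p. The text names part of them.

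Spike-in ratios of KO and WT were compared by an exact permutation test within stages (46656 arrangements). Small RNA percentages carry 95% Wilson intervals, and the length classes were chosen after the length distribution was seen. The comparison of the MII sets was set against 50 simulations of unchanged groups that share controls, with the same spread per gene in each group. Versions of the other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

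Alternatives chosen before the data were examined were RLE size factors, DESeq2, no filter on low counts, a mean CPM of at least 5, a replicate block, leaving out each library in turn, a fold change of at least 2, only the groups compared, scaling to ERCC, removal of the 10 most abundant genes of each library, and small RNA sequences with at least 10 reads. After the data were examined 3 were added: a fit without the KO-54PEA libraries, a fit of the 18 libraries from GV to 1C-20PEA, and limma voom with library weights. A change of pseudocount did not apply to counts.

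The fits were tested on simulated data with 200 changed genes. In testis, 2-fold changes were recovered in 20.9% of 67 genes, 4-fold in 94.0% of 67 and 16-fold in all of 66, and 16 of 159 calls were false, a share above the threshold of 0.05. In oocytes and embryos the first sizes tried (2-fold, 4-fold and 16-fold) gave 0 recovered genes at GV and at 33PEA. Larger sizes were then added. With these, edgeR recovered 16-fold changes in 4.48% of 67 genes at GV and 5.97% at 33PEA, and the largest size in 54.5% and 59.1% of 66, with 2 false of 41 calls and 0 of 43. Splits of the libraries, the real one included, were all 10 in testis and 25 within stages for the average, fewer than 100 because of run time.

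Replicate numbers were checked as pairs. The correlation of residuals between WT and KO libraries with the same number was −0.031, 0.0285 and −0.0686 in testis, where 0 WT libraries correlated best with their own number, and −0.0348 to 0.169 per stage in oocytes and embryos. The numbers were not taken as pairs.

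A search for genes whose WT and KO libraries do not overlap was made after the values of Tmem39a were seen. Its 5 stages (GV to 33PEA), its measure (TMM-scaled CPM) and its set of genes were chosen after a version on CPM without TMM had been looked at.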

Results

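Long RNA of golden hamsters (breed Syrian) was profiled in 32 libraries, to compare wild-type animals (WT) with animals labelled as lacking Pld6 (KO). Of these, 26 came from oocytes and early embryos and 6 from testis of animals aged 3 weeks. The oocyte and embryo libraries form 13 groups of 2. They cover WT and KO at 6 stages labelled GV, MII, 10PEA, 1C-20PEA, 33PEA and 54PEA, and a further set of KO MII oocytes labelled D321. GV oocytes still hold the germinal vesicle, the large nucleus of the growing oocyte, and MII oocytes are arrested in meiosis ready for fertilisation. The labels do not spell out PEA, 1C or D321. Testis has 3 WT and 3 KO libraries. Gene counts ranged from 1544198 (KO-54PEA replicate 2) to 11031837 (WT-MII replicate 2) in oocytes and embryos, with 4403 to 16726 genes counted, and from 31572737 to 34257661 in testis, with 21266 to 22912 genes. Levels are counts scaled to library size (CPM), given as mean ± SD with n = 2 libraries per oocyte or embryo group and n = 3 per testis group. Changes are log2 ratios, KO over WT unless stated, with adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The protocol speaks of single oocytes or embryos and names no female. Nothing in the labels says that the libraries come from separate animals, so the p-values measure only the spread between these samples, part of which can be technical. The oocyte and embryo fit takes 1 spread per gene for all stages, while libraries of a group correlated at 0.962 in WT-GV, 0.532 in KO-33PEA and −0.143 in KO-54PEA, which can make p-values too small at the late stages and too large at the early ones. Reads made by PCR are not independent molecules, so intervals and floors on counts cover counting error only.

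Pld6 encodes a phospholipase D family protein of the mitochondrial surface with a role in the making of piRNAs, the small RNAs that guide PIWI proteins. In testis it stood at 42.4 ± 8.10 CPM in WT, from 34.5 to 50.7, and at 3.72 ± 1.41 CPM in KO, from 2.63 to 5.31. This was a fall (log2 −3.51, SE 0.32, adjusted p = 2.46e-05). In GV oocytes it lay at 34.7 ± 0.578 CPM in WT and 31.6 ± 9.18 CPM in KO (adjusted p = 1). MII oocytes had 11.01 ± 3.49 CPM in WT, 4.42 ± 3.84 CPM in KO and 10.3 ± 4.66 CPM in the D321 set. At 10PEA the level was 13.3 ± 3.31 CPM in WT and 3.25 ± 4.60 CPM in KO, and at 1C-20PEA 24.7 ± 5.29 and 12.1 ± 0.699 CPM, without a call at either stage. Both KO-33PEA libraries had no Pld6 count, against 5.11 and 27.3 CPM in WT, at least 69.5-fold lower (floor of 3 counts over the group, adjusted p = 0.0214). That call was lost without WT-33PEA replicate 2, KO-33PEA replicate 1 or KO-33PEA replicate 2. All 4 libraries of 54PEA had no Pld6 count. The labels do not say which part of the gene is altered, so its counts cannot check the KO labels, and a KO library means here a library labelled KO.

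In the testis of 3-week-old KO animals most germ cell markers were lower and most Sertoli and Leydig cell markers higher. With an estimated correlation the Sertoli list had a camera adjusted p = 0.240 and the Leydig list 0.285. Of 18024 genes tested, 10459 passed the threshold, 5021 higher and 5438 lower in KO (48.0% higher), and 8215 of them differed at least 2-fold. Most genes of the piRNA pathway, of early meiosis and of pachytene and later spermatocytes fell, while these 3 lists too had a p = 0.240 each with an estimated correlation. Piwil1, a PIWI protein of pachytene spermatocytes, dropped from 403.1 ± 75.7 to 1.67 ± 1.15 CPM (log2 −7.91, SE 0.55, adjusted p = 5.25e-06). Piwil2, active earlier in the germ line, dropped from 241 ± 15.4 to 4.40 ± 1.36 CPM (log2 −5.78, SE 0.29, adjusted p = 1.54e-06). The germ cell helicase Ddx4 dropped from 236 ± 90.0 to 2.44 ± 1.53 CPM (log2 −6.59, SE 0.58, adjusted p = 1.88e-05). Piwil3 was low in both groups, at 3.37 ± 0.764 CPM in WT and 0.0316 ± 0.0312 CPM in KO.

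Among the germ cell lists, 28 of 29 measured piRNA pathway genes fell, 28 adjusted over the list alone, with a median log2 change of −4.93 (limma camera, adjusted p = 8.78e-12 over 23 lists, and 0.240 with an estimated correlation). They included Fkbp6 (log2 −6.96) and Tdrd1 (log2 −6.80), partners of PIWI proteins. Early meiosis had 24 of 25 genes lower (24 adjusted over the list alone; median −4.66; camera adjusted p = 1.92e-10, and 0.240 with an estimated correlation). Its examples were Syce3, of the synaptonemal complex, which dropped from 89.5 ± 8.68 to 0.646 ± 0.215 CPM, the cohesin subunit Stag3 (log2 −4.80) and Prdm9 (log2 −7.01), which places the breaks of meiotic recombination. All 20 genes of pachytene and later spermatocytes fell, 20 adjusted over the list alone, with a median of −6.54 (camera adjusted p = 2.44e-10, and 0.240 with an estimated correlation). Tesmin dropped from 562.5 ± 100.4 to 3.60 ± 0.534 CPM, Meig1 from 48.8 ± 17.6 to 0.0652 ± 0.00285 CPM, and the kinase Nek2 changed by log2 −5.50. Among 14 spermatogonia markers 1 rose and 9 fell, also 1 and 9 adjusted over the list alone (median −1.91; camera adjusted p = 0.00932, and 0.240 with an estimated correlation). Stra8, which starts meiosis, dropped from 50.3 ± 3.14 to 0.440 ± 0.269 CPM, with Sohlh1 (log2 −4.25) and the RNA-binding protein Dazl (log2 −4.79). Of 12 spermatid genes 1 rose and 7 fell, as many adjusted over the list alone, but the list did not pass (median −1.34; camera adjusted p = 0.0559). The acrosomal gene Dkkl1 dropped from 367 ± 105 to 1.24 ± 0.630 CPM. The cell division list of meiotic and mitotic spindle genes had 1 higher and 21 lower of 23, the same adjusted over the list alone (median −3.00; camera adjusted p = 6.69e-08, and 0.153 with an estimated correlation). Cdca8 (log2 −4.26), Espl1, which encodes separase (log2 −4.23), and the checkpoint kinase Bub1b (log2 −3.62) were among them.

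Most somatic lists moved up. Of 14 Sertoli cell markers 13 rose and none fell, 14 adjusted over the list alone (median 1.29; camera adjusted p = 0.000139, and 0.240 with an estimated correlation). Amh, the hormone of immature Sertoli cells, rose from 153 ± 24.5 CPM in WT (log2 2.72, SE 0.24, adjusted p = 1.92e-05), and Dhh (log2 1.82) and Sox9 (log2 1.32) rose as well. Leydig cell markers rose in 6 of 8, also 6 adjusted over the list alone (median 2.10; camera adjusted p = 0.00654, and 0.285 with an estimated correlation). Cyp17a1, an enzyme of androgen synthesis, went from 79.6 ± 30.8 to 1441 ± 37.1 CPM (log2 4.18), Insl3 from 99.3 ± 15.9 to 665.5 ± 123 CPM (log2 2.75), and the lipoprotein receptor Scarb1 rose by log2 1.29. Of 11 macrophage and leukocyte markers 7 rose, 7 adjusted over the list alone (median 1.19; camera adjusted p = 0.0146, and 0.307 with an estimated correlation), with Csf1r (log2 1.89), C1qc (log2 1.62) and Lyz (log2 1.14). Peritubular and vascular markers split, with 3 higher and 1 lower of 11 in both counts, over all genes and adjusted over the list alone (median 0.37; camera adjusted p = 0.395). The endothelial genes Cdh5 (log2 1.61) and Kdr (log2 1.73) rose and the smooth muscle gene Cnn1 fell (log2 −1.83). The granulosa and cumulus list shares Amh, Fshr, Inha, Star, Cyp11a1 and Lhcgr with the Sertoli and Leydig lists, and 7 of its 13 genes rose and 1 fell, 8 and 1 adjusted over the list alone (median 1.49; camera adjusted p = 0.00544, and 0.240 with an estimated correlation). Kitlg, a growth factor for germ cells, went from 61.1 ± 10.8 to 689 ± 325 CPM. Of the blood markers 2 were measured and neither passed.

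**Figure D1:**
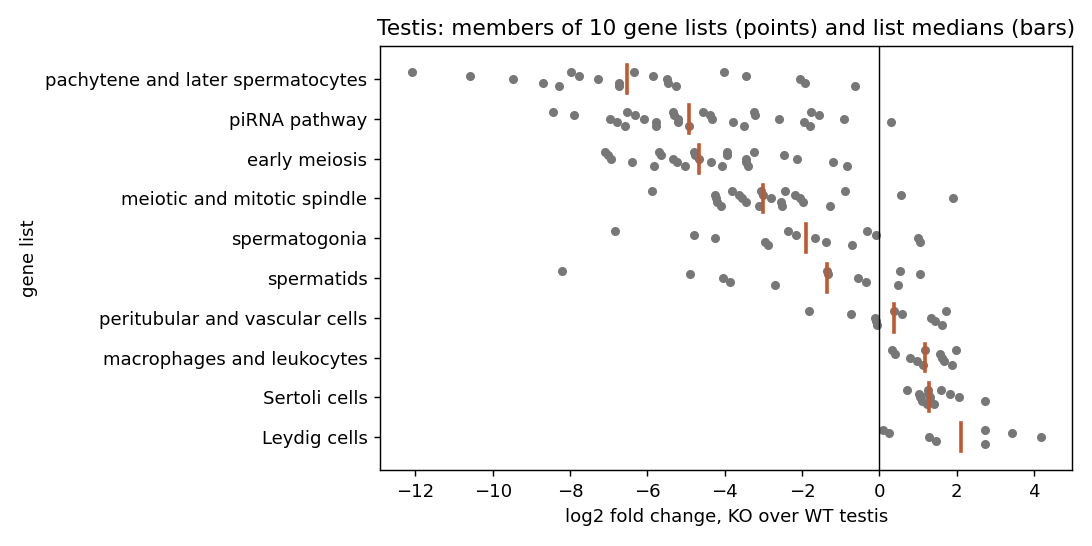
Log2 change between KO and WT testis for the members of 10 of the gene lists, 1 point per gene, with the list median as a bar. The medians of the piRNA, early meiosis and pachytene lists lie at −4.93, −4.66 and −6.54, and those of the Sertoli and Leydig lists at 1.29 and 2.10, with the same signs under both scalings tried in testis.

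Lists outside the cell types of the testis were mixed. Maternal oocyte genes had 1 higher and 8 lower of 12, 1 and 8 adjusted over the list alone (median −3.53; camera adjusted p = 0.0237, and 0.257 with an estimated correlation), with Fbxo43, a meiotic cell cycle inhibitor, at log2 −5.87. Ribosome biogenesis had 3 higher and 16 lower of 30, 3 and 16 adjusted over the list alone (median −0.61; camera adjusted p = 0.0338, and 0.378 with an estimated correlation). Npm3 (log2 −2.25) and Wdr12 (log2 −1.96) fell most clearly. Cytosolic ribosomal proteins had 20 higher and 5 lower of 78, 9 and 2 adjusted over the list alone (median 0.37; camera adjusted p = 0.0402, and 0.775 with an estimated correlation). Rpl10l, a germ cell copy of a ribosomal protein gene, dropped from 203 ± 33.6 to 4.66 ± 0.155 CPM, while Rpl39 rose by log2 1.89. Small RNA machinery had 1 higher and 8 lower of 13, with equal counts adjusted over the list alone (median −0.95; camera adjusted p = 0.0739), including Ago4 (log2 −2.52) and Drosha (log2 −0.95). DNA methylation and repeat silencing split into 5 higher and 8 lower of 21 in both counts, over all genes and adjusted over the list alone (median −0.30; camera adjusted p = 0.674). Uhrf1, which recruits the maintenance methyltransferase, dropped from 128 ± 1.96 to 4.001 ± 2.69 CPM, and the demethylation enzymes Tet2 (log2 2.91) and Tet3 (log2 2.43) rose. The interferon list had 4 higher and 1 lower of 14 in both counts, over all genes and adjusted over the list alone (median 0.38; camera adjusted p = 0.156). The p53 and apoptosis list had 9 higher and 5 lower of 23, 10 and 5 adjusted over the list alone (median 0.44; camera adjusted p = 0.221), with Sesn1 (log2 1.66) and Gadd45a (log2 1.62) higher and Chek1 lower (log2 −2.39). The stress list had 5 higher and 6 lower of 18, 5 and 7 adjusted over the list alone (median −0.44; camera adjusted p = 0.674), with the integrated stress factor Atf4 higher (110.2 ± 7.32 to 310.8 ± 82.9 CPM). Maternal mRNA storage and decay had 5 higher and 9 lower of 23 in both counts, over all genes and adjusted over the list alone. Its median was 0.22, its mean −0.70 and the direction of the test down (camera adjusted p = 0.674), and Ybx2, which stores messages in germ cells, dropped from 1092 ± 262 to 5.01 ± 1.81 CPM. Embryonic factors had 2 higher and 8 lower of 16, 2 and 9 adjusted over the list alone (median −1.05; camera adjusted p = 0.0681), with Tfap2c at log2 −3.56. Oxidative phosphorylation had 1 higher and 11 lower of 59, 0 and 5 adjusted over the list alone (median −0.11; camera adjusted p = 0.576), with Sdhb at log2 −1.54. Mitochondrial dynamics had 4 higher and 2 lower of 16 in both counts, over all genes and adjusted over the list alone (median 0.14; camera adjusted p = 0.395), with Miga1 (log2 2.02) and Mief2 (log2 1.91) higher. Mitochondrial transcripts had 0 measured genes. With an estimated correlation 0 of the 12 list calls in testis held. The fry test passed for 17 of 23 lists. It asks whether a list moves on balance one way against no change, and not against other genes. Because 10459 of 18024 genes passed, it says little about a list in particular.

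The largest single rises in testis were of genes outside the lists. Slitrk5, a neuronal membrane protein, rose from 0.263 ± 0.0729 CPM in WT (log2 4.72, SE 0.41, adjusted p = 1.63e-05). Sftpc, known as a lung surfactant protein, went from 1.72 ± 0.0852 to 33.7 ± 13.5 CPM (log2 4.29), and the protease Tmprss13 from 2.87 ± 0.490 to 41.5 ± 7.63 CPM (log2 3.85). Reep1 (log2 4.12), the vitamin D receptor Vdr (log2 3.88) and the ferroxidase Heph (log2 3.87) also rose. Among the falls, Marchf11 had no count in KO and 37.1 ± 17.7 CPM in WT, at least 1126-fold lower. The sperm genes Spata16 (at least 489.9-fold lower), Cfap65 (at least 430.0-fold) and Fsip2 (at least 240.8-fold) likewise had no count in KO, each against a floor of 3 counts over the group. Leaving out any 1 of the 6 libraries kept the call of all 90 genes named by the rule, and the count stayed between 8180 and 11524.

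**Figure D2:**
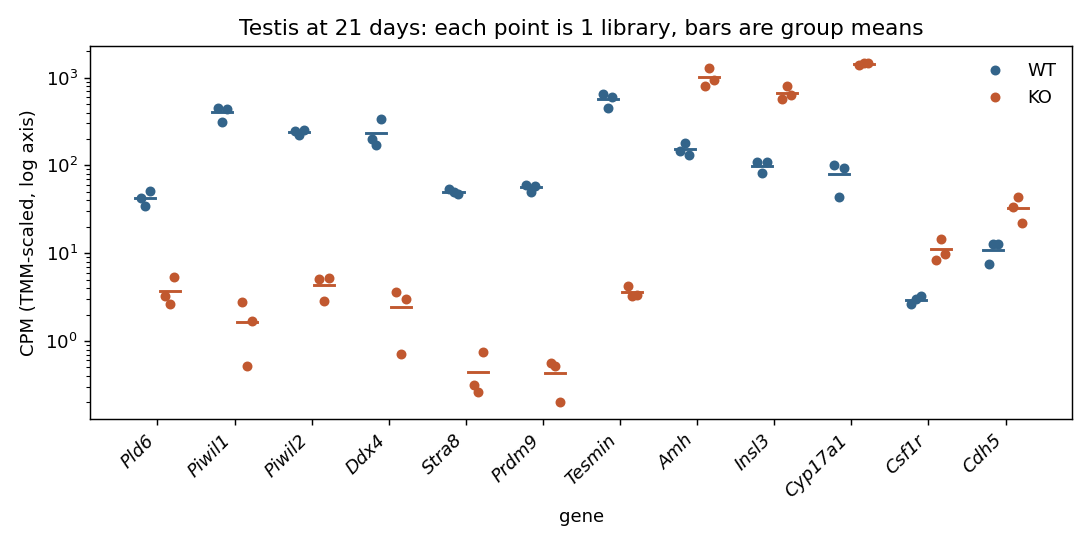
CPM in the 6 testis libraries on a log axis for genes of the germ cell and somatic lists, with a point per library and the mean as a bar. Piwil1 lies at 403.1 CPM in WT and 1.67 CPM in KO, and Insl3 at 99.3 and 665.5 CPM.

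In oocytes and embryos, the endogenous RNA counted per spike-in count was highest in WT-GV and lowest in KO-54PEA among the group means. Each oocyte or embryo received the same volume of an ERCC spike-in mix, so the ratio of gene counts to ERCC counts follows the RNA captured and counted. Libraries of 1 group could differ widely in this ratio, as in KO-10PEA with 114.4 and 7.72. At MII, 10PEA and 1C-20PEA replicate 2 had the lower ratio in both WT and KO. At GV and 54PEA the genotypes differed in this, and at 33PEA and in D321 replicate 2 had the higher ratio. The permutation test below did not use replicate numbers. A change in the ratio need not be a change in the amount of RNA. It was 267 ± 12.9 in WT and 184 ± 45.4 in KO at GV, 74.0 ± 35.7 and 49.6 ± 37.2 at MII, 45.3 ± 27.6 and 61.1 ± 75.4 at 10PEA, and 34.7 ± 32.4 and 64.3 ± 59.8 at 1C-20PEA. At 33PEA it was 7.83 ± 0.736 in WT and 4.24 ± 0.719 in KO. At 54PEA it was 19.9 ± 2.46 in WT and 0.544 ± 0.365 in KO, with geometric means 41.3-fold apart, and ERCC made up 55.5% and 77.8% of the counts of the KO-54PEA libraries. The mean log2 difference over 6 stages was −1.19 (exact permutation test within stages, two-sided, p = 0.0848). Without 54PEA it was −0.35 (exact permutation p = 0.497). The p fell below the threshold without KO-10PEA replicate 1 (−1.51, exact p = 0.0277), WT-1C-20PEA replicate 2 (−1.38, exact p = 0.0434) or KO-1C-20PEA replicate 1 (−1.38, exact p = 0.0435).

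**Figure D3:**
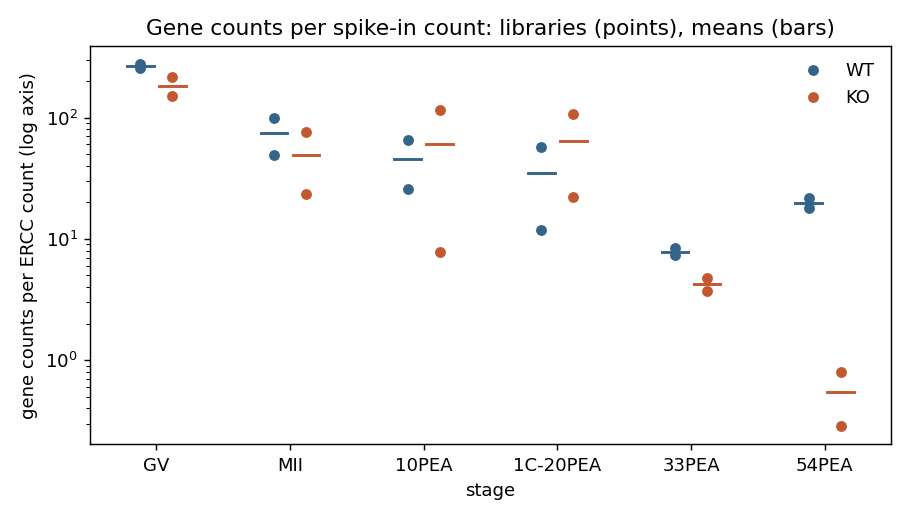
Gene counts per ERCC count in each of the 24 WT and KO oocyte and embryo libraries (log axis) by stage, with a point per library and the mean as a bar. The KO-54PEA mean is 0.544 and the WT-54PEA mean 19.9.

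The choice of scaling moved the median change of several comparisons. Under edgeR's TMM scaling the median log2 change of all 17294 genes tested between KO and WT was 0 at GV, −0.11 at MII, 0 at 10PEA, 1C-20PEA and 33PEA, −1.08 at 54PEA and −0.56 in the average over stages. Scaling to the ERCC counts moved it to −0.50, −0.68, 0.17, 0.26, 0, −5.05 and −1.11 in that order. Median-of-ratios size factors (RLE) moved it to 0 at MII, −0.11 at 1C-20PEA and −0.56 at 54PEA. Along the WT time course the median was −0.38 from GV to MII (−0.52 under RLE, −2.64 under ERCC), 0 from 10PEA to 1C-20PEA (0.18 under RLE), −1.24 from 1C-20PEA to 33PEA (−3.29 under ERCC) and 0 from 33PEA to 54PEA (0.87 under ERCC). Changes below are relative to TMM, and the other direction is given where a scaling turned the median of a list.

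From GV to 1C-20PEA no single gene passed between KO and WT in the edgeR fit of all 26 libraries, while other edgeR fits called some. Piwil1 was at 137 ± 5.19 CPM in WT and 122 ± 11.3 CPM in KO at GV, and at 59.4 ± 1.13 and 63.2 ± 9.77 CPM at MII. Piwil3, a PIWI protein of the oocyte, was at 35.7 ± 7.54 and 26.2 ± 3.96 CPM at GV and at 18.1 ± 1.58 and 4.54 ± 1.20 CPM at MII. Ddx4 was at 719 ± 13.9 and 513 ± 78.5 CPM at GV. Piwil2 was at 10.3 ± 6.62 and 10.6 ± 2.29 CPM at GV and at 2.82 ± 0.512 and 0.0709 ± 0.1002 CPM at MII. At 10PEA Piwil3 was at 26.3 ± 12.04 CPM in WT and 8.03 ± 11.4 CPM in KO, and at 1C-20PEA at 8.80 ± 12.4 and 32.8 ± 4.53 CPM. By edgeR 0 genes passed at GV, with 28 at an unadjusted p under 0.05, 12 passing by DESeq2 and 183 by limma voom. At MII 0 passed (707 unadjusted; 220 by DESeq2; 204 by voom), at 10PEA 0 (266 unadjusted; 83 by DESeq2; 32 by voom) and at 1C-20PEA 0 (1048 unadjusted; 569 by DESeq2; 119 by voom). Leaving out KO-1C-20PEA replicate 2 gave 1. An edgeR fit of the 18 libraries from GV to 1C-20PEA called 8 genes at MII, 7 at 10PEA and 374 at 1C-20PEA, and a fit without the KO-54PEA libraries 3, 4 and 45 in that order. Without a filter on low counts it was 5, 6 and 22, with only the groups compared 22 at GV, and with RLE 1 at MII. In simulated data, a 16-fold change at GV was recovered in 4.48% of the genes that carried it, so this fit missed most changes of that size.

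Some lists moved in these stages without a gene that passed. At GV the Sertoli list (5 genes; median 2.54; camera adjusted p = 0.000717, and 0.250 with an estimated correlation), the granulosa and cumulus list (10 genes; median 1.26, 0.91 with genes absent from a group at their bound; adjusted p = 0.00573, and 0.319 with an estimated correlation) and the interferon list (10 genes; median 0.51; adjusted p = 0.00141, and 0.497 with an estimated correlation) were higher in KO. Under ERCC scaling the medians of the 3 lists were 1.98, 0.58 and 0.02. No member passed, adjusted over all genes or adjusted over the list alone. Inha, a hormone subunit of granulosa and Sertoli cells that is on the first of these lists and on the granulosa list, had 0.198 and 0.473 CPM in the WT libraries and 1.40 and 18.6 CPM in the KO libraries. At 10PEA ribosomal proteins (median 0.61, 0.59 at the bound; adjusted p = 0.00812, and 0.982 with an estimated correlation) and oxidative phosphorylation (median 0.76; adjusted p = 0.00258, and 0.982 with an estimated correlation) were higher in KO. At 1C-20PEA ribosomal proteins were lower (median −1.37, −1.32 at the bound; adjusted p = 7.92e-05, and 0.982 with an estimated correlation), 6 of 78 adjusted over the list alone, with a median of −0.18 under ERCC scaling. Rpl7a stood there at 380.0 ± 244 CPM in WT and 24.5 ± 14.6 CPM in KO.

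At 33PEA, part of the maternal transcripts stood higher in KO than in WT embryos, and part of the ribosomal and nucleolar ones lower. With an estimated correlation none of the 3 lists passed (camera adjusted p = 0.0735 for maternal oocyte genes, 0.888 for ribosomal proteins and 0.683 for ribosome biogenesis). The oocyte survival gene Bcl2l10 stood at 7058 ± 599 CPM in KO and 364 ± 119 CPM in WT (log2 4.28, SE 0.60, adjusted p = 0.000636). The oocyte importin Kpna7 stood at 819 ± 135 and 116 ± 4.12 CPM (log2 2.82), and the maternal gene Nlrp14 at 1484 ± 457 and 189 ± 101 CPM (log2 2.98). Polr1c, a subunit of RNA polymerases I and III, was at 0.405 ± 0.573 CPM in KO, far under WT (log2 −11.44, SE 1.89, adjusted p = 0.00287). Of 17294 genes, 978 were higher and 772 lower (55.9% higher), 1750 in all. The share of higher genes was 23.6% without WT-33PEA replicate 2 (87 higher and 281 lower), 41.1% without a filter, 41.85% at a mean CPM of at least 5, 43.5% by voom and 48.02% without the KO-54PEA libraries. The Kpna7 call was lost without WT-33PEA replicate 2, and the Nlrp14 call without that library or KO-33PEA replicate 2.

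By list, 7 of 25 maternal oocyte genes rose and none fell at 33PEA, 11 adjusted over the list alone (median 2.20; camera adjusted p = 0.000567, and 0.0735 with an estimated correlation). Ribosomal proteins fell in 28 of 78, 55 adjusted over the list alone (median −3.12; camera adjusted p = 1.39e-16, and 0.888 with an estimated correlation). Rpl5 dropped to 51.3 ± 0.559 from 1212 ± 60.3 CPM (log2 −4.56, SE 0.87, adjusted p = 0.00423). Ribosome biogenesis fell in 9 of 30, 16 adjusted over the list alone (median −3.78; camera adjusted p = 1.03e-07, and 0.683 with an estimated correlation), with Nolc1 at log2 −3.67. Among 28 piRNA genes 2 rose and 4 fell, 2 and 5 adjusted over the list alone. Gtsf1, a piRNA silencing factor, rose (150.6 ± 23.4 against 14.1 ± 0.995 CPM; log2 3.42), and Piwil2 fell from 352 ± 3.12 to 2.12 ± 2.24 CPM (log2 −7.37, SE 2.33, adjusted p = 0.0466). The maintenance methyltransferase Dnmt1 (from 279 ± 43.1 CPM in WT) and the de novo enzyme Dnmt3a (log2 3.62) rose and the corepressor Trim28 fell (log2 −5.06), among 3 higher and 2 lower of 21 silencing genes, 3 and 2 adjusted over the list alone, whose median was −0.02 and mean 0.35. The synaptonemal genes Sycp3 (log2 3.54) and Hormad1 (log2 4.28) rose, among 3 of 23 early meiosis genes (3 higher and 1 lower adjusted over the list alone). The cell cycle kinases Cdk1 (log2 5.39) and Bub1b (log2 3.35) rose, among 3 higher and 2 lower of 24 spindle genes, 7 and 4 adjusted over the list alone (median 0.89; camera adjusted p = 0.680). The cleavage embryo genes Zfp42 (log2 −3.55) and Dppa4 (log2 −4.91) fell, as did the m6A reader Ythdf2 (log2 −3.89), while the deadenylase subunit Pan2 rose (123 ± 58.7 against 6.27 ± 1.19 CPM). The ATP synthase subunit Atp5mc1 (log2 −5.13) and the complex I subunit Ndufs8 (log2 −5.41) fell, among 1 higher and 6 lower of 59 oxidative phosphorylation genes, 1 and 7 adjusted over the list alone. The calls of Piwil2, Dnmt3a, Trim28 and Dppa4 were lost without any 1 of the 4 libraries. Without WT-33PEA replicate 1 those of Gtsf1, Bub1b and Pan2 were lost too. Without WT-33PEA replicate 2 it was Nolc1, Gtsf1, Dnmt1, Sycp3, Hormad1, Cdk1, Bub1b, Ythdf2, Pan2 and Ndufs8. Without KO-33PEA replicate 1 it was Nolc1, Bub1b, Zfp42 and Ndufs8, and without KO-33PEA replicate 2 Nolc1, Dnmt1, Sycp3, Hormad1, Ythdf2 and Pan2.

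The largest changes at 33PEA were in genes absent from 1 group. Rpp30, a subunit of RNase P, had no count in KO and 1537 ± 178 CPM in WT, at least 7053-fold lower. Psmc6 (at least 6675-fold), Supt7l (at least 2423-fold) and Surf2 (at least 1845-fold) behaved alike. Asxl3 (at least 232.7-fold), Tbc1d32 (at least 184.1-fold), Dtnb (at least 162.9-fold), Tmem9 (at least 159.3-fold) and Adgrf3 (at least 135.7-fold) were counted in KO alone. The calls of Asxl3, Tbc1d32, Dtnb and Adgrf3 were lost without WT-33PEA replicate 2, and those of Tbc1d32 and Adgrf3 also without WT-33PEA replicate 1 or KO-33PEA replicate 2. The count at 33PEA rested on each library. It was 1129 without WT-33PEA replicate 1, 368 without WT-33PEA replicate 2, 1217 without KO-33PEA replicate 1 and 998 without KO-33PEA replicate 2. With only the 4 libraries of the stage in the fit 0 genes passed, DESeq2 gave 4605 and scaling to ERCC 71, of which 3 were higher and 68 lower. Of 53 genes named here by the rule and called, 10 kept the call without any 1 library, among them Bcl2l10, Polr1c, Rpl5, Rpp30 and Tmem9, and 46 lost it under ERCC scaling.

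At 54PEA the KO libraries held few genes and much spike-in, and relative to the remaining RNA part of their maternal transcripts were higher and part of their transcripts for respiration and cell division lower. With an estimated correlation the maternal list passed (camera adjusted p = 0.00343), while oxidative phosphorylation (0.699) and spindle genes (0.668) did not. Cdk1, the kinase of mitosis, had no count in KO and 1019 ± 354 CPM in WT, at least 2865-fold lower (adjusted p = 1.41e-05). The kinetochore motor Cenpe dropped from 689 ± 113 to 0.479 ± 0.677 CPM (log2 −10.44, SE 1.35, adjusted p = 1.66e-05). Bcl2l10 stood at 205 ± 92.5 CPM in KO and 6.19 ± 2.03 CPM in WT (log2 5.04, SE 0.62, adjusted p = 1.18e-05), and the zona pellucida gene Zp4 at 1597 ± 1174 and 49.9 ± 25.1 CPM (log2 5.00). In all, 699 genes were higher and 2921 lower (19.3% higher), 3620 of 17294. Under ERCC scaling it was 94 higher and 7351 lower (1.26% higher), and with the stage's own 4 libraries 105 higher and 2973 lower.

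Maternal oocyte genes had 13 higher and 3 lower of 25 in KO-54PEA, 14 and 3 adjusted over the list alone, with a median of 2.88 that turned to −1.47 under ERCC scaling (2.85 at the bound; camera adjusted p = 3.99e-08, and 0.00343 with an estimated correlation). Oxidative phosphorylation fell in 24 of 59, 29 adjusted over the list alone (median −3.55, −3.07 at the bound; camera adjusted p = 7.56e-07, and 0.699 with an estimated correlation). The complex I subunits Ndufa10 (at least 364.6-fold), Ndufb8 (at least 234.1-fold) and Ndufa12 (at least 163.8-fold) had no count in KO. Ribosomal proteins fell in 14 of 78, also 14 adjusted over the list alone (median −2.32; camera adjusted p = 0.000690, and 0.982 with an estimated correlation), among them Rpl10a (log2 −4.80). Spindle genes had 1 higher and 10 lower of 24, 1 and 12 adjusted over the list alone (median −2.05; camera adjusted p = 0.00862, and 0.668 with an estimated correlation). Ribosome biogenesis fell in 9 of 30, 10 adjusted over the list alone (camera adjusted p = 0.169), with Nop56 (log2 −3.46) and Rrp12 (at least 215.8-fold lower). The mitofusin Mfn2 had no count in KO (at least 47.4-fold lower) and Mfn1 fell by log2 −9.54, among 5 of 16 mitochondrial dynamics genes, 6 adjusted over the list alone. In the silencing group, Hells, a chromatin remodeller needed for DNA methylation, had no count in KO (at least 544.4-fold lower). The pluripotency regulator Lin28a was higher in KO, at 221 ± 150 against 6.26 ± 1.99 CPM (log2 5.14). Myc (at least 138.0-fold) and the chaperone Hspa5 (at least 543.2-fold) had no count in KO. Ddx4 was called higher in KO (82.3 ± 116 against 2.10 ± 2.64 CPM), and the call was lost without WT-54PEA replicate 2. It rested on KO-54PEA replicate 2 with 678 counts, since KO-54PEA replicate 1 had 0. Outside the lists, Arl10 (at least 1068-fold) and Rasgrp2 (at least 615.5-fold) were counted in KO alone, and Ppa1 (at least 1638-fold) and Pum3 (at least 1387-fold) in WT alone. The Spearman correlation between the KO-54PEA libraries across genes was −0.143, against 0.822 between the WT-54PEA libraries. Of 63 genes named by the rule and called, 49 kept the call without any 1 library and 14 lost it under ERCC scaling.

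**Figure D4:**
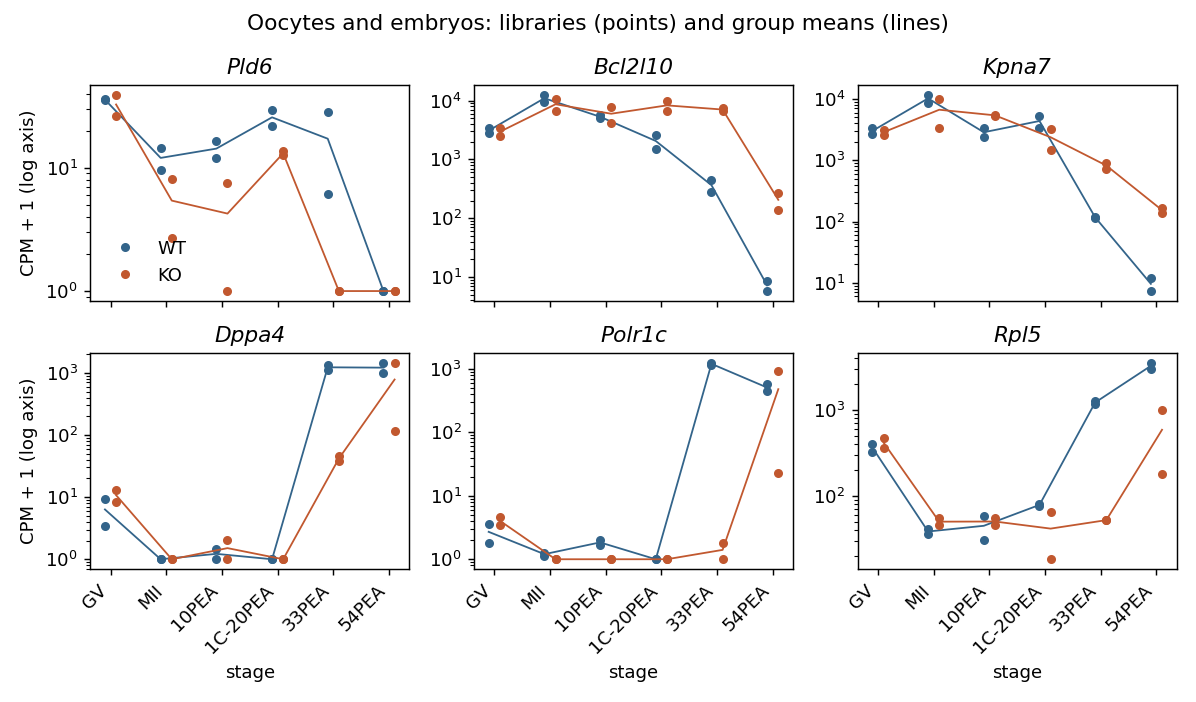
CPM plus 1 by stage in WT and KO oocyte and embryo libraries (log axis) for genes named in the report, with a point per library and lines through the means. Bcl2l10 lies at 364 CPM in WT and 7058 CPM in KO at 33PEA.

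In the average over the 6 stages some maternal transcripts were higher in KO and some ribosomal and mitochondrial ones lower, with unlike values by stage. The median of the maternal oocyte list was −0.07 at GV, −0.19 at MII, 0.29 at 10PEA and −0.36 at 1C-20PEA, against 2.20 at 33PEA and 2.88 at 54PEA. Under RLE it turned to 0.06 at GV and 0.16 at MII. Under ERCC scaling it turned to 0.50 at 1C-20PEA and −1.47 at 54PEA. The median of ribosomal proteins was −0.10, −0.13, 0.61, −1.37, −3.12 and −2.32 in the order of stages, and under RLE it turned to 0.02 at GV and 0.15 at MII. Bcl2l10 rose (log2 1.85, SE 0.22, adjusted p = 6.08e-05), as did the ubiquitin hydrolase Uchl1 (log2 1.37, SE 0.27, adjusted p = 0.00351), the meiotic kinase Aurkc (log2 1.30, SE 0.25, adjusted p = 0.00253) and Dnmt1 (log2 1.00, SE 0.22, adjusted p = 0.00714). The calcium-binding protein Tesc rose as well (log2 2.98, SE 0.32, adjusted p = 1.85e-05). Rpl7a (log2 −1.53) fell. Of 17294 genes 292 rose and 1080 fell (21.3% higher), 1372 in all, against 31 and 2112 (1.45% higher) under ERCC scaling and 34.4% higher by DESeq2. Maternal oocyte genes rose in 8 of 25, 9 adjusted over the list alone, with a median of 0.56 that turned to −0.31 under ERCC scaling (camera adjusted p = 3.48e-08, and 0.00343 with an estimated correlation). Ribosomal proteins fell in 15 of 78, 32 adjusted over the list alone (median −1.04; camera adjusted p = 2.97e-10, and 0.982 with an estimated correlation). Oxidative phosphorylation fell in 10 of 59, 14 adjusted over the list alone (median −0.97; adjusted p = 0.00108, and 0.982 with an estimated correlation), and ribosome biogenesis in 3 of 30, 4 adjusted over the list alone (median −0.97; adjusted p = 0.000275, and 0.982 with an estimated correlation). Of 53 genes named by the rule and called in the average, 25 kept the call without any 1 library, among them the 6 genes above, and 28 lost it, while 14 lost it under ERCC scaling. The count was 870.0 without KO-GV replicate 1, 852 without KO-GV replicate 2, 3008 without KO-54PEA replicate 1 and 2121 without KO-54PEA replicate 2. A direct F test of the differences between stages called 1625 genes as having a KO effect that was not the same at all 6 stages. The test was not run without 54PEA, where the KO libraries correlated at −0.143. Which stages carry the differences was therefore not told apart.

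The D321 set of KO MII oocytes was compared with the WT and the other KO MII oocytes. Against WT MII 0 genes passed by edgeR in the fit of all libraries (278 unadjusted; 115 by DESeq2; 233 by voom), and against the other KO MII oocytes 0 (786 unadjusted; 255 by DESeq2; 151 by voom). With only the groups compared in the fit, 25 genes passed against WT MII and 0 against the other KO MII oocytes. Ddx4 was at 1279 ± 229 CPM in D321, 1287 ± 246 CPM in WT and 717 ± 526 CPM in KO, Piwil1 at 58.4 ± 4.01, 59.4 ± 1.13 and 63.2 ± 9.77 CPM, and Piwil3 at 11.7 ± 2.78, 18.1 ± 1.58 and 4.54 ± 1.20 CPM. Ribosomal proteins were higher in D321 than in WT (median 0.87, 0.85 at the bound; camera adjusted p = 3.35e-05, and 0.982 with an estimated correlation) and than in KO (median 0.75, 0.70 at the bound; adjusted p = 0.0275, and 0.982 with an estimated correlation), 3 of them adjusted over the list alone in the latter. Under ERCC scaling these medians were 1.51 and 2.07, and under RLE the latter was 0.41. Oxidative phosphorylation was higher than in WT (median 0.53; adjusted p = 0.0194, and 0.982 with an estimated correlation). The median of all genes was 0 against WT (0.33 under ERCC) and 0.14 against KO (0 under RLE, 1.20 under ERCC). The KO and D321 changes against the shared WT libraries correlated at 0.368 over 11754 genes, where simulated unchanged groups gave 0.499 (0.487 to 0.524). In 59.0% of genes the sign was the same, against a simulated 66.8% (65.6% to 67.8%). The simulation gave each MII group the same spread per gene. The real libraries of a group correlated at 0.914 in WT-MII, 0.734 in KO-MII and 0.89 in D321. The lower observed values therefore cannot show that the 2 changes are less alike than those of unchanged groups. With the MII libraries alone in the fit each comparison called 1 gene, and it was the same gene, Tmem39a. The 2 WT MII libraries serve both comparisons, and a split with 1 of them for each comparison was not made. Tmem39a, chosen after its values were seen, had 0 counts in both WT MII libraries, 543 and 552 in KO and 1064 and 758 in D321.

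Along the WT time course, fits of only the groups compared called 5540 genes from GV to MII and 4327 from 1C-20PEA to 33PEA, and voom 6183 and 7165. In the fit of all libraries these steps had 35 and 3567. The 35 genes from GV to MII were all lower at MII. They included the ribosomal protein genes Rpl35 (51.6 ± 21.0 to 0.274 ± 0.0216 CPM; log2 −7.47, SE 1.09, adjusted p = 0.00496), Rpl19 (log2 −6.91) and Rpl18 (log2 −8.46), and Drap1 (at least 1033-fold lower). Ribosomal proteins fell in 9 of 78, 60 adjusted over the list alone (median −3.87; camera adjusted p = 2.53e-30, and 0.557 with an estimated correlation), and oxidative phosphorylation in 1 of 59, Atp5mc1 (log2 −4.43), with 21 adjusted over the list alone (median −3.15; adjusted p = 2.44e-11, and 0.402 with an estimated correlation). The p53 list was up with a median of 0 and a mean of 0.42 (adjusted p = 0.0495, and 0.319 with an estimated correlation). Of 6 genes named by the rule and called, 0 kept the call without any 1 library and 5 lost it under ERCC scaling. The count was 15 without WT-GV replicate 1 or replicate 2 and 0 without either WT-MII library, against 5540 with the GV and MII libraries alone in the fit and 978 by DESeq2. From MII to 10PEA 0 genes passed by edgeR in the fit of all libraries (477 unadjusted; 163 by DESeq2; 942 by voom), and 1286 with only the groups compared. The macrophage list was higher there (6 genes; median 1.80; camera adjusted p = 0.0175, and 0.304 with an estimated correlation; 1 adjusted over the list alone), with Csf1r at 50.5 ± 9.87 CPM in MII and 613 ± 85.3 CPM at 10PEA. Mitochondrial dynamics was higher too (median 1.01; adjusted p = 0.0206, and 0.788 with an estimated correlation). From 10PEA to 1C-20PEA 0 passed (544 unadjusted; 155 by DESeq2; 152 by voom). There the silencing list was lower (median −0.76; adjusted p = 0.0158, and 0.982 with an estimated correlation), and ribosomal proteins (median 0.93, 0.92 at the bound; adjusted p = 0.00108, and 0.982 with an estimated correlation) and oxidative phosphorylation (median 1.09; adjusted p = 0.00707, and 0.982 with an estimated correlation) were higher. Under ERCC scaling their medians were 0.15 and 0.28.

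From 1C-20PEA to 33PEA most of the maternal list fell in WT embryos and most of the ribosomal proteins rose. With an estimated correlation neither list passed (camera adjusted p = 0.0735 and 0.660). Of 17294 genes 857 rose and 2710 fell (24.03% higher), against 172 and 3156 (5.17% higher) under ERCC scaling. Maternal oocyte genes fell in 17 of 25, 19 adjusted over the list alone (median −3.60, −3.35 at the bound; camera adjusted p = 0.000737, and 0.0735 with an estimated correlation). Kpna7 dropped from 4362 ± 1395 to 116 ± 4.12 CPM (log2 −5.24, SE 0.66, adjusted p = 9.38e-05) and the oocyte transcription factor Nobox from 514 ± 74.4 to 17.5 ± 6.36 CPM (log2 −4.87). Btg4, an adaptor of maternal mRNA decay, dropped from 1552 ± 675 to 4.63 ± 5.19 CPM (log2 −8.39). Ribosomal proteins rose in 56 of 78 and fell in 1, 67 and 1 adjusted over the list alone (median 4.53; camera adjusted p = 9.87e-26, and 0.660 with an estimated correlation), with Rpl35 at log2 7.86. Ribosome biogenesis rose in 10 of 30, 11 adjusted over the list alone (median 2.56; camera adjusted p = 1.68e-06, and 0.709 with an estimated correlation), with Nip7 at log2 8.92, and a median of 0.62 under ERCC scaling. Dppa4, a gene of the cleavage embryo, went from no count to 1223 ± 146 CPM (at least 6673-fold), with Znhit3 (at least 8566-fold) and Polr1c (at least 6631-fold), while Rspo2 (at least 937.9-fold) and Atp23 (at least 873.4-fold) were lost. The piRNA genes Gtsf1 (log2 −4.20) and Piwil1 (log2 −5.03) fell and the piRNA-trimming enzyme Pnldc1 rose (log2 3.47). The Piwil1 call was lost without WT-33PEA replicate 2, and the Pnldc1 call without that library, WT-1C-20PEA replicate 1 or WT-1C-20PEA replicate 2. Of 58 genes named by the rule and called, 29 kept the call without any 1 library and 29 lost it, and 13 lost it under ERCC scaling. The count was 2285 without WT-1C-20PEA replicate 1, 1825 without WT-1C-20PEA replicate 2, 1863 without WT-33PEA replicate 1 and 1141 without WT-33PEA replicate 2.

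From 33PEA to 54PEA WT embryos lost further maternal messages. Bcl2l10 dropped from 364 ± 119 to 6.19 ± 2.03 CPM (log2 −5.87, SE 0.65, adjusted p = 2.93e-05), Lin28a from 944 ± 42.1 to 6.26 ± 1.99 CPM (log2 −7.23) and the kinase Wee2, a brake on the oocyte cell cycle, from 707 ± 286 to 8.77 ± 4.92 CPM (log2 −6.33). Cdk1 went from 2.08 ± 2.93 to 1019 ± 354 CPM (log2 8.91, SE 1.38, adjusted p = 0.000456) and the checkpoint kinase Chek1 from 9.52 ± 2.18 to 225 ± 26.3 CPM (log2 4.56). Maternal oocyte genes fell in 13 of 25 (1 rose and 16 fell adjusted over the list alone; median −3.47, −3.07 at the bound; camera adjusted p = 4.54e-10, and 0.00331 with an estimated correlation). Oxidative phosphorylation rose in 6 of 59, 8 adjusted over the list alone (median 2.19; camera adjusted p = 2.31e-06, and 0.709 with an estimated correlation), with Ndufa5 (at least 417.7-fold) and Ndufb7 (at least 183.0-fold). Ribosomal proteins rose in 1 of 78 and in 0 adjusted over the list alone (median 1.41; adjusted p = 0.00138, and 0.982 with an estimated correlation). The call of Piwil1 (at least 12.9-fold lower) and those of Pld6 (at least 81.1-fold lower) and Ddx4 (log2 −6.61) pointed down. That of Piwil1 was lost without WT-33PEA replicate 1 or either WT-54PEA library, that of Pld6 without WT-33PEA replicate 2 or either WT-54PEA library, and that of Ddx4 without WT-54PEA replicate 2. The Ndufa5 call was lost without WT-33PEA replicate 1. Of 37 genes named by the rule and called, 13 kept the call without any 1 library and 24 lost it, and all 37 lost it under ERCC scaling. Of 17294 genes 427 rose and 797 fell (34.9% higher), against 1 and 0 under ERCC scaling, 47.4% higher by DESeq2, 50.3% with the 4 libraries alone in the fit (435 and 430.0) and 58.9% by voom (1969 and 1376). The count was 731 without WT-33PEA replicate 1, 917 without WT-33PEA replicate 2, 581 without WT-54PEA replicate 1 and 441 without WT-54PEA replicate 2.

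Small RNA was analysed in 1 WT-GV and 1 WT-54PEA library, without replicates, so values are given with no test of the stages. The other small RNA samples of the series were not analysed here. GV oocytes were rich in small RNAs of 28 to 30 nt, the length of longer piRNAs, at 29.0% of 4305443 reads (95% Wilson interval 29.0% to 29.1%), while WT-54PEA had 1.14% of 4662344 reads (1.13% to 1.15%). Of the GV reads of that length 77.7% began with T, and 51.6% of those of 54PEA. A start with T was not particular to that length. In GV it was at 95.1% for 18 to 20 nt, 71.4% for 21 to 22 nt and 84.5% for 23 to 24 nt. In 54PEA these shares were 83.2%, 75.9% and 83.4%. Reads of 21 to 22 nt, the length of most microRNAs, made up 9.86% in GV and 36.4% in 54PEA, those of 23 to 24 nt 19.0% and 12.8%, and those of 18 to 20 nt 26.3% and 40.4%. The sequence TCAGGACATGCTGAGTCT, 18 nt long, had 87311 reads in GV and 34688 in 54PEA. TATATGGTTCAGAATTTCACT, 21 nt long, had 47377 reads in GV and 129056 in 54PEA, and TGAAATTCAAAGCTTGTATACT, 22 nt long, 1642 and 54768. The libraries shared 51934 sequences, which held 86.4% of the GV reads and 92.2% of the 54PEA reads. No reference genome was used here, so the sequences carry no gene name or position.

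**Figure D5:**
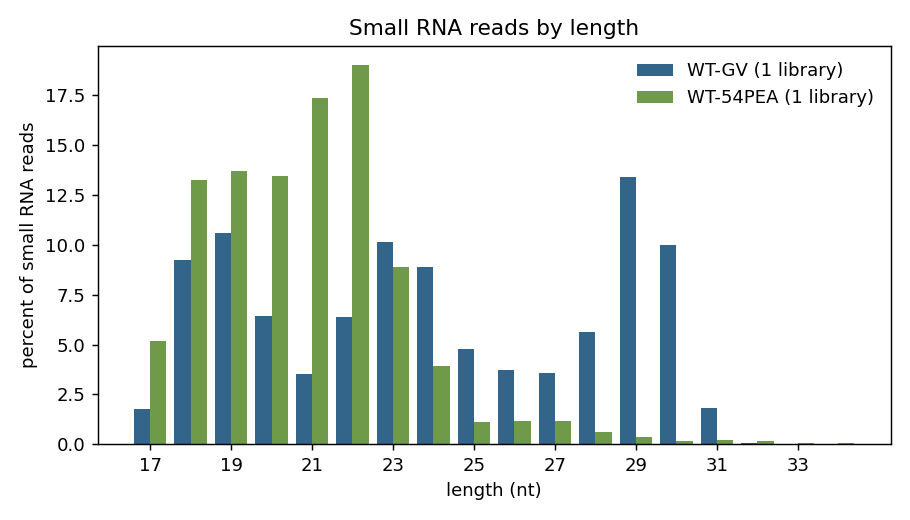
Percent of small RNA reads by read length in nt in the WT-GV and WT-54PEA libraries, 1 library each. Reads of 28 to 30 nt make up 29.0% in WT-GV and 1.14% in WT-54PEA.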

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

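The F test of the differences between stages was planned, and the tests below had their limits written before they were run on the data, but the patterns they address were picked from the same data.

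The test named "KO effect differs between stages", a direct test of the differences between groups, found 1625 genes. The count was 3236 without KO-54PEA replicate 1 and 2774 without KO-54PEA replicate 2.

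In testis, germ cell genes were lower and somatic genes higher in KO. A lower share of germ cells with no other change would raise all somatic lists alike. Their medians spanned 1.72 log2 units (permutation of list membership, p = 2e-04), from 0.374 for peritubular and vascular cells to 2.10 for Leydig cells. The permutation takes genes as independent, and its p does not measure the spread between libraries. In these 6 libraries the somatic lists thus did not rise alike, and whether that holds beyond them was not tested. Unequal shares of the somatic cell types were not tested. Of the 10 splits of the 6 libraries, 1 gave as many genes as the real one with 10459, and the highest other gave 0, but 10 splits are too few for a share under 0.05. The loss of germ cells, changes within Sertoli and Leydig cells and changes in the share of each somatic cell type may all contribute, and these were not told apart.

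At 33PEA, genes higher in KO could be genes that WT libraries missed by chance. Of the 978 such genes 85.3% were at least 2-fold lower in WT-54PEA than in WT-1C-20PEA, against 43.8% of all 17294. A gene called higher must be counted in KO-33PEA, and the set of all genes was not matched for that. The test therefore cannot decide on chance dropout in WT. Delayed or arrested development could also give the pattern. The KO change at 33PEA followed the reverse of the WT course with a Spearman correlation of 0.499. WT-33PEA itself lay towards WT-54PEA on that course, so other KO profiles can give a positive correlation too. No null was drawn for this, so 0.499 does not tell delay from other causes. A median position over 10070 genes was also taken between WT-1C-20PEA (0) and WT-54PEA (1), with no limit written in advance. The KO-33PEA libraries lay at 0.246 and 0.27, and the WT-33PEA libraries at 0.816 and 0.983. Both KO-54PEA libraries lay at 1, but a gene without a count in WT-54PEA and in the library lies at 1 by construction. These libraries held 5381 and 4403 genes, so their position cannot tell a late state from missing genes. The limit written in advance for the Spearman correlation was just above 0.499 and was not reached, so delayed or arrested development stays open.

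At 54PEA, a low ratio of gene to ERCC counts could come from more spike-in. If reads were independent molecules, the KO-54PEA libraries then would hold as many genes as WT-54PEA libraries thinned to the same gene counts. The highest of the 4 ratios to these was 0.478, and the highest ratio to thinned WT-33PEA libraries was 0.572. Fewer genes were thus found than thinning alone gives. Reads made by PCR are not independent molecules, so the test cannot exclude excess spike-in. Degraded or dying embryos, failed amplification and a true loss of RNA could each give the low ratio of gene to ERCC counts and were not tested. For the average over stages, 1 of 25 splits drawn within stages gave as many genes as the real 1372, the real split itself, and the highest other gave 1082. This share is under 0.05 but is the smallest that 25 splits can give. Other splits also gave 990 and 984 genes, so chance is not excluded. The count itself was 870.0 without KO-GV replicate 1, 852 without KO-GV replicate 2, 3008 without KO-54PEA replicate 1 and 2121 without KO-54PEA replicate 2.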

How the results depend on the processing

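The alternatives named without the KO-54PEA libraries, GV to 1C-20PEA and voom were chosen after the data were examined. Values are numbers of genes past the threshold, and for values that moved the cause was not tested unless the setting itself leaves libraries out.

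In testis no alternative moved the count of 10459 by over 1.5 times, and the replicate block gave 9691. The block gave 1566 at 33PEA, 3525 at 54PEA, 1324 in the average, 27 from GV to MII, 3459 from 1C-20PEA to 33PEA and 1125 from 33PEA to 54PEA. The correlation of residuals gave no ground to pair the libraries by replicate number. At MII, 10PEA and 1C-20PEA, though, replicate 2 had fewer gene counts per ERCC count in both WT and KO.

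DESeq2 gave 12 at GV, 220 at MII, 83 at 10PEA, 569 at 1C-20PEA, 4605 at 33PEA, 3096 in the average, 4389 for the test that the KO effect differs between stages, 115 for D321 against WT and 255 against KO. Along the WT course it gave 978 (GV to MII), 163 (to 10PEA), 155 (to 1C-20PEA), 5994 (to 33PEA) and 3142 (to 54PEA). Voom with library weights gave 183, 204, 32, 119 and 2809 at GV, MII, 10PEA, 1C-20PEA and 33PEA, 3079 in the average, 7342 for the differences between stages, 233 and 151 for D321 against WT and KO, and 6183, 942, 152, 7165 and 3345 along the course. ERCC scaling gave 71 at 33PEA, 7445 at 54PEA, 2143 in the average, 1 from GV to MII and 1 from 33PEA to 54PEA. RLE gave 1 at MII and 64 from GV to MII. A mean CPM of at least 5 gave 2 for D321 against KO and 76 from GV to MII. No filter gave 5 at MII, 6 at 10PEA, 22 at 1C-20PEA, 3128 for the differences between stages, 2 and 8 for D321 against WT and KO, 4 from MII to 10PEA and 102 from GV to MII.

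Only the groups compared gave 22 at GV, 0 at 33PEA (edgeR; 5243 at an unadjusted p under 0.05 in the fit of all libraries and 4605 by DESeq2), 25 for D321 against WT, 5540 from GV to MII and 1286 from MII to 10PEA. Without the KO-54PEA libraries the counts were 3 at MII, 4 at 10PEA, 45 at 1C-20PEA, 3390 at 33PEA, 1 and 2 for D321 against WT and KO, 298 from GV to MII and 2247 from 33PEA to 54PEA. Only GV to 1C-20PEA libraries gave 8 at MII, 7 at 10PEA, 374 at 1C-20PEA, 1 and 3 for D321 against WT and KO, 1114 from GV to MII, 38 to 10PEA and 9 to 1C-20PEA.

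Leaving out each library in turn gave 8180 to 11524 in testis, 0 to 0 at GV, MII and 10PEA, 0 to 1 at 1C-20PEA, 368 to 1217 at 33PEA, 2857 to 4062 at 54PEA, 852 to 3008 in the average, 1334 to 3236 for the differences between stages, 0 to 0 for D321, 0 to 15 from GV to MII, 0 to 0 for the next 2 steps, 1141 to 2285 from 1C-20PEA to 33PEA and 441 to 917 from 33PEA to 54PEA. The spike-in difference ran from −1.51 to −0.86. Turned in direction were Ddx4 at 54PEA without KO-54PEA replicate 2 (fitted log2 −7.07) and Arg2 at 54PEA under ERCC scaling (−1.95). Without WT-54PEA replicate 1 the fitted log2 of Ddx4 was 8.36. These Ddx4 values rest on 0 counts in KO-54PEA replicate 1 and 2 counts in WT-54PEA replicate 2. Their size is therefore not a measured fold.

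In the settings that left out no single library, 3110 values of named genes kept their side of the threshold and 279 lost it. Of those lost, 128 were under ERCC scaling and 86 with only the groups compared. Of those kept, 358 came from the fold change of at least 2, which reuses the p-values of the main fit. A gene without an adjusted p under a setting was not counted there. With at least 10 reads per small RNA sequence, reads of 28 to 30 nt made up 30.1% in WT-GV and 0.979% in WT-54PEA.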

Other observations

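The genes of this part and the search for them were chosen after the values were seen, while the adjusted p-values of Kif2a come from comparisons planned before.

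Tmem39a, a membrane protein gene, lay higher in every KO library than in any WT library from GV to 33PEA. It had 0 to 3.54 CPM in 10 WT libraries and 31.5 to 168 CPM in 10 KO libraries, and 169.9 and 110.2 CPM in the D321 set. Kif2a, a kinesin that takes apart microtubule ends, had 16.3 to 136 CPM in WT and 230.5 to 2100.0 CPM in KO, and 973.3 and 937.3 CPM in D321. Nacc1, a transcriptional regulator, had 0 to 18.3 CPM in WT and 27.5 to 108.5 CPM in KO, and 30.3 and 22.1 CPM in D321. At 54PEA Tmem39a had 16.5 and 4.84 CPM in WT and 109.8 and 0 CPM in KO, and in testis 59.4, 54.4 and 56.1 CPM in WT and 56.0, 49.3 and 55.7 CPM in KO. The average log2 change of Kif2a was 3.24 (SE 0.45, edgeR adjusted p = 0.000244), but at 54PEA Kif2a had 98.1 and 149 CPM in WT and 63.0 and 0.728 CPM in KO (log2 −1.95, adjusted p = 0.188). Nacc1 had 10.1 and 3.92 CPM in WT-54PEA and no count in KO-54PEA.

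These genes came from a search over 17294 genes that followed the sight of Tmem39a. It found 23 genes higher and 11 lower in KO at each of 5 stages, 34 in all, where chance gives 0.0257% per gene. Of 3888 ways to part the libraries of each stage, 21 (0.54%) gave as many, the real one included. The median of the other ways was 1 and the highest 112, so some other groupings part the libraries more strongly. In 5 genes all 10 KO libraries stood above all 10 WT libraries, and in 0 below. Of these, LOC121134132 had 0 to 2.50 CPM in WT, 3.09 to 29.05 CPM in KO and 2.24 and 1.75 CPM in D321, within the WT range. Further genes of the higher set were Msmo1, Hsp90aa1, Aurkc, Lsm8 and Ficd, and of the lower set St7l, Gfm2, Dcaf13, Snx10 and Rab7a. The choice of stages and of the measure after the values were seen makes the share a description of these libraries and not a test.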
